A study of Mus musculus with 3 samples.

How the data were processed

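RNA immunoprecipitated from white fat of Flag-FTO transgenic mice was sequenced on an Illumina instrument, per the labels, in 2 libraries with an anti-Flag M2 antibody and 1 with IgG. The lysate was precleared on protein-G beads, incubated with the antibody, washed 6 times per the labels' protocols, and the RNA was freed with proteinase K and extracted with acid phenol. The submitters' processing notes name CASAVA 1.7, Bowtie 0.12.2 and the genome build mm8. The program that counted reads per gene, its annotation release and its strand setting are not given in the sources used here. The deposited table holds raw counts per Ensembl gene, 1 column per library, whole numbers with no normalization, and columns were matched to libraries by the sample numbers in the labels. A second deposited table lists lipid genes with a Flag count, an IgG count and their ratio, and the ratio equals the unscaled division of those counts wherever the IgG count is above 0. An image of read densities was not used here.

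Gene positions, RNA classes, spans and transcript GC come from the GENCODE M21 annotation of GRCm38, matched by Ensembl identifier (37693 of 39179 matched). All positions in the text are in that build and none are in mm8. Symbols are those of the deposited table, apart from 27 that a spreadsheet had turned into dates, which took the annotation's name. Because the counting rules are not known, genes that overlap or lie inside each other, antisense pairs and near-identical copies are treated as uncertain: of 107 named genes, 43 overlap another gene with counts, and for 22 that gene has at least 50% as many Flag-IP counts.

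Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17587, while 8136 had 0 counts in all libraries. TMM factors were 0.840, 0.936 and 1.27, for Flag-IP 1, Flag-IP 2 and IgG-IP. A normalized count is the count divided by the library's effective size and multiplied by the mean effective size. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of Flag-IP against IgG-IP with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom per gene, all from the 2 Flag-IP libraries, and a common dispersion of 0.0359 (a biological coefficient of variation of 0.189). The standard error of a log2 fold change is its size divided by the square root of the F statistic. No gene had finite prior degrees of freedom, so these p-values and standard errors rest on a spread shared between genes. A gene's own difference between the Flag-IP libraries does not enter them. Log2 ratios of single libraries use edgeR log2 CPM with a prior count of 2. A gene with 0 counts in the IgG-IP library has only a lower bound, taken against a floor of 3 counts in that library. Intervals and floors cover counting error only.

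Gene lists were tested with camera and fry (limma 3.58.1) and by the percentile of the median among 10000 random lists of the same size matched on mean expression. The 31 lists cover adipocyte and lipid pathways, other cell types of fat and neighbouring tissue, RNA methylation, translation, mitochondria and noncoding RNA, and were fixed before the data were examined, as were the main test, a set of other settings and the rule for named genes. That rule takes Fto and Angptl4, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 50 counts and the same sign in both Flag-IP libraries, the 3 members of each list with the largest fold change among those with a mean of at least 20 counts, and the 10 genes of the authors' lipid list with the largest fold change. Some genes that the rule takes are not reported here. Genes named outside it (mt-Rnr1, mt-Ti, Gm26924, Itsn1, Hdgfrp2, Gm11149, Snord15b, Rpl10, and Acsm5, Insig1 and Slc27a4 of the lipid list) and all genes first named in the closing section were chosen after their values were seen. The tests by RNA class, GC content, span and host gene were also chosen after the data were seen.

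The settings fixed in advance were RLE, total-count and upper-quartile scaling, no filter and a mean of at least 50 counts, DESeq2 1.42.0, a likelihood ratio test with common dispersion, a test against a 1.5-fold change, prior counts of 0.5 and 10, an estimated correlation in camera, and leaving out each Flag-IP library. Added after seeing the data were scaling to genes under 10000 counts, lowess corrections on gene span, transcript GC and both, and a fit without genes that hold a structural RNA gene. Under the lowess corrections camera was run on values with the trends subtracted more than once. Its results there decide nothing and are not given. List medians and tests of single genes under these corrections had each trend removed once. The trends were fitted over genes of all RNA classes, apart from the most highly counted. For short genes the span trend therefore rests partly on structural RNA and mitochondrial genes themselves. Random draws used fixed seeds, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The main test was tested on simulated data with the means and sizes of this comparison over 17587 genes, 50 of them changed by each of 4 factors, none of them among the weakly counted genes (mean of at least 50 counts): it recovered 100% of 4-fold and 44% of 2-fold increases, 96% of 4-fold and 24% of 2-fold decreases, and called 7 of 17387 unchanged genes. All simulated libraries, IgG-IP included, had the dispersion of the fit and no GC trend. The simulation therefore cannot show errors from an IgG-IP library that varies otherwise or from such a trend.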

Results

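RNA that came down with a Flag-tagged FTO protein was compared with RNA that came down with a nonspecific IgG, both from white fat of 16-week-old C57BL/6 mice carrying a Flag-FTO transgene and fasted overnight. FTO is an enzyme that removes methyl groups from adenosines in RNA. In an RNA immunoprecipitation the antibody pulls the tagged protein out of a lysate together with whatever RNA is attached to it, and the IgG pull-down measures the RNA that sticks without the tag being recognised. The data are 3 libraries, 2 of the Flag immunoprecipitation (Flag-IP 1 and Flag-IP 2) and 1 of the IgG immunoprecipitation (IgG-IP), as counts for 39179 genes. The labels do not say whether the libraries came from separate animals, so the spread between the Flag-IP libraries could be technical only. The p-values of single genes rest on that spread, shared between genes, and the IgG-IP library adds none to it. Tests of RNA classes, and camera with its preset correlation, compare genes with each other, so their p-values do not measure a spread between samples. Triplets of counts are given throughout as Flag-IP 1, Flag-IP 2 and IgG-IP.

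The libraries held 98227791, 95824218 and 74176962 counts, but few genes took almost all of them. The 28 genes with at least 100000 counts in any library held 97.6%, 97.6% and 97.0% of the counts in Flag-IP 1, Flag-IP 2 and IgG-IP. The largest was Gm26924, a noncoding gene (GRCm38, GENCODE M21, chromosome 17, 39846958 to 39848788) that overlaps an annotated ribosomal RNA gene. It took 29.8% and 33.3% of the counts in the Flag-IP libraries and 41.7% in the IgG-IP library, where the 95% Wilson interval, which covers counting error only, is at most 0.0112 percentage points to either side. All other genes shared what remained, and the median tested gene had 24, 26 and 25 counts. Differences in weakly counted genes were therefore often not detectable at this depth. The 2 Flag-IP libraries differed by more than sampling noise, with a chi-square of 4.82 per degree of freedom over 14912 genes, which does not show whether they are separate animals. They were treated as 2 replicates, as their labels number them.

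The comparison of Flag-IP with IgG-IP asked which RNAs the tagged FTO carried above background. Structural RNAs were higher in the Flag-IP libraries, among them small RNAs of the nucleus and nucleolus and signal recognition particle RNA. The long noncoding RNA Malat1 and both mitochondrial ribosomal RNAs were higher too. The mitochondrial messenger and transfer RNA genes were lower, as were a group of protein-coding genes led by Dnajc22, Phip and Eif3f. Of 17587 genes tested, 981 were higher and 1015 were lower in Flag-IP by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. A further rule of size, which needs no test, found 1596 genes at least 2-fold higher and 746 at least 2-fold lower in both Flag-IP libraries, against 2207 genes at least 2-fold apart between the Flag-IP libraries themselves. Over the 4979 genes with a mean of at least 50 counts, the SD of the log2 difference was 0.36 between the Flag-IP libraries, and 0.83 and 0.77 between each of them and the IgG-IP library. The lone IgG-IP library has no replicate, and the model assumes that it varied as the Flag-IP libraries did. With scaling to total counts in place of TMM factors the split was 342 higher to 3008 lower, since that scaling moved all log2 fold changes by a median of -0.52, and DESeq2, which gave no adjusted p for 15684 of the 17587 genes, called 131 higher and 145 lower.

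The transcript of Fto itself had 230, 291 and 300 counts, a log2 fold change of -0.08 ± 0.22 (SE). All 3 libraries came from transgenic mice, so this value does not check the labels. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase and is the target this study is known for, had 4, 12 and 6 counts. Its log2 fold change was 0.52 ± 1.27 (SE), with an edgeR adjusted p = 0.847. The Flag-IP libraries lay on opposite sides of the IgG-IP library, at 4.31 and 11.9 normalized counts against 5.65, and no difference was detectable at this depth.

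Among genes past the threshold with a mean of at least 50 counts, the 10 with the largest increases were all structural RNAs, and 8 of them had under 30 counts in the IgG-IP library without being at 0 there. Rnu5g, a gene for the U5 RNA of the spliceosome (chromosome 9, 65201726 to 65201841, GRCm38), had 310, 293 and 5 counts, a log2 fold change of 6.01 ± 0.42 (SE). The small nuclear RNA genes Gm24924 (5.28 ± 0.33), Gm24871 (5.25 ± 0.39), Gm25099 (4.98 ± 0.36), Gm25313 (4.97 ± 0.37), Gm26444 (4.88 ± 0.32) and Gm23238 (4.86 ± 0.36) followed on the log2 scale. Snora74a, a guide RNA for pseudouridylation, had 148, 56 and 4 counts. The guide RNAs Snora81 (122, 53 and 0 counts) and Snora15 (92, 75 and 0) were at least 32.5-fold and at least 30.7-fold higher, taking a floor of 3 counts in the IgG-IP library. These genes belong to families of similar copies or lie inside other genes, so their single values are uncertain.

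Annotated RNA classes, tested for enrichment with Fisher's exact test over 20 classes, showed the same division. Of 36 small nuclear RNA genes, 33 were higher and 0 were lower (adjusted p = 1.56e-37). The counts were 26 of 30 for small nucleolar RNAs (adjusted p = 2.75e-28), 41 of 58 for genes of the rRNA class (adjusted p = 1.56e-37), 5 of 7 for small Cajal body RNAs (adjusted p = 3.41e-05) and 9 of 14 for the miscellaneous class that holds 7SK and signal recognition particle RNA (adjusted p = 3.92e-08). Copies within a class share reads, so these genes are not independent of each other. Of the list of structural noncoding RNAs fixed before the data were examined, 7 of 8 tested members were higher and 0 lower, with a median log2 fold change of 3.03. Rnu1a1, the U1 RNA that recognises 5' splice sites, had 996, 715 and 41 counts (4.52 ± 0.31, SE). Rn7sk, which holds back transcription elongation, had 654, 351 and 37 (3.91 ± 0.30), and Rnu11 of the minor spliceosome had 38, 32 and 4 (3.22 ± 0.70). The list passed the camera test (adjusted p = 3.75e-06), which was lost with an estimated correlation (adjusted p = 0.816). The median was 1.97 with a trend on span removed and 1.34 with span and GC removed. Those trends were fitted with structural RNAs included, so they can take up part of the increase itself. Camera subtracted the trends more than once under these corrections and decides nothing there.

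**Figure D1:**
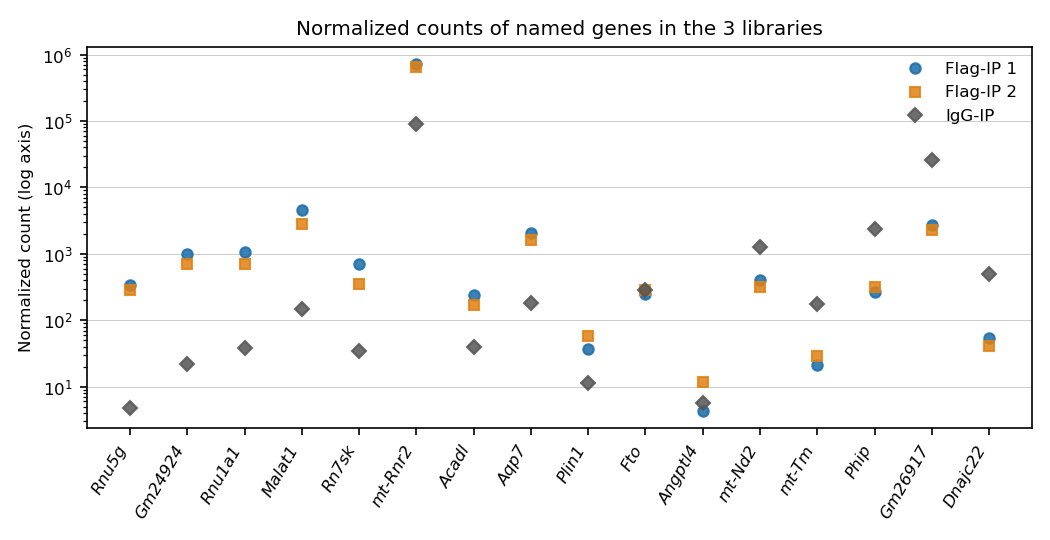
Normalized counts (log axis) of 16 named genes in the Flag-IP 1, Flag-IP 2 and IgG-IP libraries, 1 point per library. Rnu5g had 312 normalized counts on average in the Flag-IP libraries against 4.71 in IgG-IP, Dnajc22 had 47.7 against 504.9, and Fto 268 against 283.

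Among long noncoding RNAs, Malat1, a nuclear RNA of the splicing compartment (chromosome 19, 5795690 to 5802672, GRCm38), had 4243, 2858 and 159 counts, a log2 fold change of 4.63 ± 0.30 (SE). Snhg1, whose introns encode small nucleolar RNAs, was higher too, with 85, 68 and 18 counts. Its identifier is not in the annotation used here, so counts of small RNA genes inside it could not be found or taken off. Its increase is therefore uncertain. Gas6 on this list encodes a secreted protein ligand and not a noncoding RNA, and was lower with 46, 56 and 188 counts. In all, 3 of 13 list members were higher, 1 was lower and 9 did not pass, and adjusted over the list alone 4 were higher. The list as a whole did not pass camera.

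The mitochondrial genome divided by RNA type. mt-Rnr2, the large ribosomal RNA (GRCm38, mitochondrial positions 1094 to 2675), had 661533, 650803 and 95938 counts, a log2 fold change of 2.91 ± 0.35 (SE), and mt-Rnr1, the small one, had 40631, 49643 and 22077. All 13 protein-coding mitochondrial genes were lower, among them mt-Nd2 (369, 325 and 1363; -1.84 ± 0.21 on the log2 scale) and mt-Nd3 (58, 31 and 158; -1.68 ± 0.30), subunits of respiratory complex I. All 22 mitochondrial transfer RNA genes were lower as well (Fisher's exact test, adjusted p = 9.02e-27), with mt-Tm at 20, 29 and 188 counts and mt-Tq, which overlaps mt-Ti, at 30, 38 and 222. The list of mitochondrially encoded genes had a median of -1.31 and passed camera (adjusted p = 0.000255, and adjusted p = 0.816 with an estimated correlation). Its transcripts had a median GC content of 36.0%, against 48.5% for all tested genes, and the list median was -0.43 with a trend on GC alone removed. That median was -2.11 with span removed and -1.29 with span and GC removed. The span trend was fitted with the short structural RNAs included, so the size of these 2 medians depends partly on them. Camera subtracted the trends more than once under these corrections and decides nothing there. Nuclear genes of oxidative phosphorylation showed no such shift, with 2 of 37 higher, 0 lower and a median of -0.03. Those were Ndufv2 (1.80 ± 0.38) and Atp5o (1.28 ± 0.29), and the 180251, 160403 and 77117 counts of Atp5o nearly equal those of Itsn1 beside it (180199, 160356 and 77062), so they cannot be assigned to either gene. Ndufa10, with a log2 fold change of 1.05, did not pass.

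Of the 10 largest decreases among genes past the threshold with a mean of at least 50 counts, 2 were the mitochondrial transfer RNA genes mt-Tm (-2.81 ± 0.32) and mt-Tq (-2.57 ± 0.29). The other 8 were nuclear genes. Dnajc22, a co-chaperone gene (chromosome 15, 99093170 to 99104737, GRCm38), had 50, 42 and 536 counts, a log2 fold change of -3.40 ± 0.24 (SE). The noncoding gene Gm26917, which lies next to Gm26924, had 2554, 2269 and 27365 (-3.37 ± 0.24). Phip (249, 315 and 2530; -3.04 ± 0.22), the translation initiation factor gene Eif3f (113, 98 and 824; -2.83 ± 0.22), the membrane protein gene Stom (292, 255 and 1868; -2.63 ± 0.21) and the centrosomal protein gene Cep85 (141, 202 and 1122; -2.58 ± 0.21) followed. Dmp1, known from bone and dentin matrix, had 30, 33 and 209 counts, and the adenylyl cyclase gene Adcy6 had 212, 230 and 1430. No reads per position were used here, so it is not known which part of each gene these counts came from.

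GC content moved with the comparison. Protein-coding genes called higher had a median transcript GC of 55.3% (779 genes), those called lower 42.7% (890 genes) and those that passed in neither direction 48.9% (13251 genes). Across 9084 protein-coding genes with a mean of at least 20 counts, which are not independent replicates, Spearman's rho between GC and log2 fold change was 0.64, and between GC and the difference of the 2 Flag-IP libraries it was 0.03. From the lowest to the highest of 10 equal groups by GC the median log2 ratio to IgG-IP went from -0.71 to 0.72 in Flag-IP 1 and from -0.65 to 0.70 in Flag-IP 2.

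**Figure D2:**
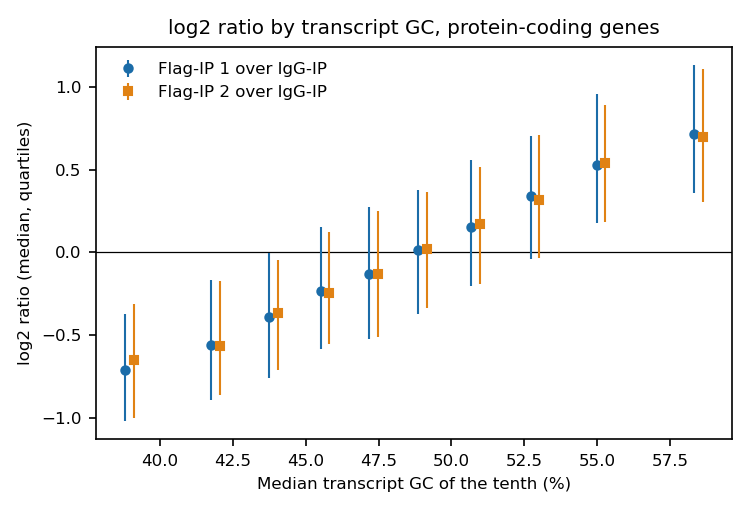
Median log2 ratio of each Flag-IP library to the IgG-IP library (vertical axis, points; lines span the quartiles over genes) in 10 equal groups of protein-coding genes by transcript GC (horizontal axis, percent). Both libraries run from about -0.7 at a median GC of 39.0% to about 0.7 at 58.5%.

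Of the genes that mark white adipocytes, 3 of 17 were higher in the Flag-IP libraries and the other 14 did not pass. Aqp7, the glycerol channel of fat cells, had 1932, 1631 and 196 counts (log2 fold change 3.32 ± 0.27, SE), and the lipid droplet coat proteins Plin4 (30, 34 and 4; 3.09 ± 0.72) and Plin1 (34, 59 and 12; 2.06 ± 0.51) were higher. The median of the list was 1.04. The list passed camera (adjusted p = 0.0146) but not with an estimated correlation (adjusted p = 0.816), and its median over single libraries was 1.52 in Flag-IP 1 and 0.46 in Flag-IP 2. With trends on span, GC or both removed the median was 0.55, 0.90 and 0.60, and camera decides nothing under those corrections. The median rests on weakly counted genes: over the 3 members with a mean of at least 50 counts it was -0.30. Plin4 shares its locus with Hdgfrp2, which had 59, 35 and 19 counts.

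Enzymes of fatty acid and triglyceride synthesis had a median of 0.77, with 4 of 23 higher and 0 lower. Scd1, a fatty acid desaturase, had 65, 49 and 22 counts (1.51 ± 0.42, SE), and Dgat2, which makes triglyceride from diglyceride, had 50, 42 and 21 (1.26 ± 0.45). Gpam, which starts glycerolipid synthesis, had 32, 20 and 12 counts and did not pass. Secreted adipokines and hormones had a median of 1.05 with 0 of 14 past the edgeR threshold. Over the 2 members with a mean of at least 50 counts that median was 0.077. Leptin (Lep) had 37, 20 and 12 counts, Angptl2 had 29, 30 and 12, and Vegfa had 36, 27 and 14. These lists passed camera (adjusted p = 0.0255 and 0.0146) and failed with an estimated correlation (adjusted p = 0.816 for both). Median GC was 53.0% for the synthesis list, 50.8% for the adipokines and 50.2% for the adipocyte markers. With trends on gene span and GC removed, the medians of these 3 lists were 0.35, 0.53 and 0.60, and camera decides nothing under that correction.

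Other lipid lists went both ways. In lipolysis, 3 of 16 genes were higher, among them Plin1 and the adenosine receptor gene Adora1 (51, 27 and 15 counts; log2 fold change 1.51, and 0.91 without Flag-IP 1), and 2 were lower, among them Gnas, the stimulatory G protein subunit (133, 121 and 304). Adjusted over the list alone 4 were higher and 3 lower. In fatty acid uptake, Lrp1 was higher (111, 120 and 53) and the fatty acid transporter gene Cd36 lower (75, 72 and 150) among 15 genes, while Lmf1 (123, 81 and 68) did not pass. In fatty acid oxidation, Acadl, the long-chain acyl-CoA dehydrogenase, was higher with 220, 173 and 42 counts (2.36 ± 0.30, SE), Hadhb was 1 of 2 lower genes (14, 23 and 54), and 18 of 21 did not pass. Cholesterol synthesis had 0 of 19 genes past the edgeR threshold: Lss had 28, 30 and 21 counts, and Fdft1 18, 26 and 44. Among brown fat genes Prdm16 was higher (339, 384 and 214) and Ppargc1a lower (49, 70 and 118), and 8 of 10 did not pass, among them Otop1 (11, 23 and 34). Of the fasting and glucocorticoid genes, Fkbp5 was higher with 3171, 3346 and 1503 counts (1.25 ± 0.24, SE), and 13 of 14 did not pass, Pck1 (34, 16 and 12) and Tsc22d3 (22, 15 and 30) included. In insulin signalling, Pik3ca (27, 41 and 76) was among 3 lower genes, 1 was higher and 17 did not pass, Tsc2 (30, 38 and 16) included. The median of that list was 0.13 while its mean was -0.03 and camera's direction was down.

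The authors also deposited a lipid list of 31 distinct genes with a Flag count, an IgG count and their ratio. Its Flag counts equal those of Flag-IP 2 for all 31 genes, and its IgG counts equal those of the IgG-IP library, so the ratios in the authors' deposited table leave out Flag-IP 1 and are not scaled for depth. Of the 22 genes tested here 4 were higher and 0 lower, with a median of 1.43 and all 22 fold changes above 0. The higher genes were Acadl, the sterol exporter gene Abcg1 (61, 58 and 21), Cyb5r3, which passes electrons to lipid enzymes (130, 98 and 41), and Ppard, a fatty acid-sensing receptor (84, 102 and 36). Others with large fold changes did not pass: Pmvk (13, 10 and 2), Acot8 (14, 18 and 5), Cyp11a1 (12, 11 and 4), Mvk (18, 24 and 8), Prkab1 (30, 16 and 9) and Lcat (15, 5 and 0). The study chose these genes on these samples, so their shared direction, the camera p of 8.58e-08 (p = 0.107 with an estimated correlation) and the 4 genes past the threshold when adjusted over the list alone are not independent evidence. The median GC of the list was 54.5%. Its median log2 fold change was 0.85 with a trend on GC removed and 0.64 with span and GC removed, and camera decides nothing under those corrections.

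Flag-IP 1 played no part in the ratios of that list. Its ratios still divide by the same IgG-IP counts (a median of 6 over the list), so they are not an independent look. Over the 25 genes with IgG-IP counts, the lowest ratio in Flag-IP 2 was 1.75, and 14 (56%) reached that value in Flag-IP 1. The cutoff was taken from the list's own Flag-IP 2 ratios, so all 25 meet it there by construction. In Flag-IP 1, 4 of them lay below the IgG-IP library: Angptl4 with 4 against 6 counts, Acsm5 with 4 against 8, Insig1 with 2 against 4 and Slc27a4 with 4 against 5. The median unscaled ratio was 2.33 in Flag-IP 2 and 2.0 in Flag-IP 1. For comparison, 4679 of the 19776 genes with at least 4 counts in Flag-IP 2 and any in IgG-IP (23.7%) reached a ratio of 1.75, and 57.7% of those reached it in Flag-IP 1 as well.

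**Figure D3:**
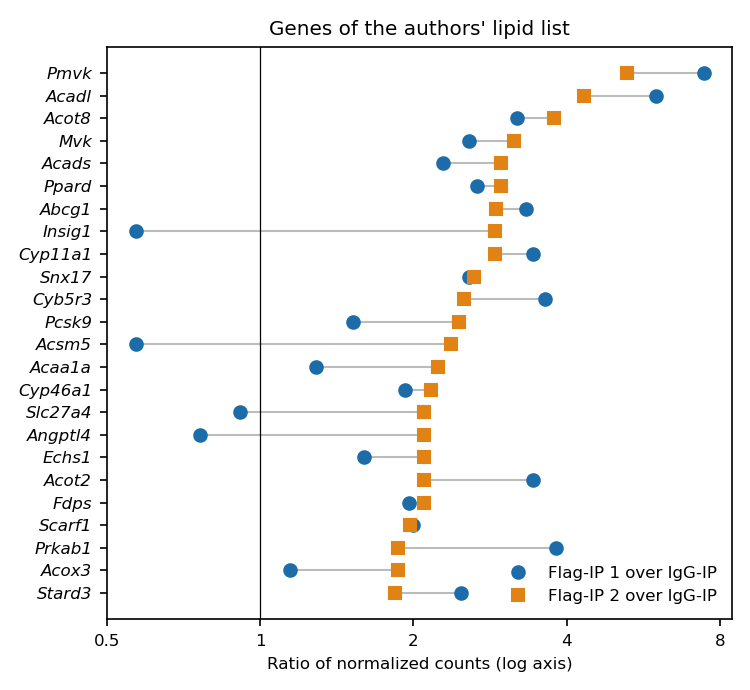
Ratio of normalized counts to the IgG-IP library (horizontal log axis) for 24 of the 25 genes of the authors' lipid list with IgG-IP counts, 1 circle for Flag-IP 1 and 1 square for Flag-IP 2 per gene. The squares all lie above 1, and 4 circles lie below it; over all 25 genes the medians were 2.45 in Flag-IP 2 and 2.29 in Flag-IP 1.

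Lists of other cell types had medians as high as 0.84 (skeletal muscle), 0.78 (smooth muscle and pericytes), 0.66 (nerve) and 0.52 (fibroblasts and matrix, 0.22 without Flag-IP 1), and none passed camera. With no filter the skeletal muscle list did (median 1.02, adjusted p = 0.0484), as did the white adipocyte list at the same adjusted p. With a trend on GC removed, the medians were 0.25 (skeletal muscle), 0.30 (smooth muscle), 0.032 (fibroblasts) and 0.52 (nerve). Among fibroblast and matrix genes 5 of 21 were higher and 0 lower, including Col5a1 (182, 157 and 84) and Timp2 (73, 57 and 34). Col6a1 passed with 167, 39 and 48 counts because of Flag-IP 1, and without that library its log2 fold change was -0.23. Of smooth muscle and pericyte genes Lmod1 (51, 47 and 21) was 1 of 2 higher genes of 10, and adjusted over the list alone 4 were higher, while Cspg4 (45, 40 and 19) and Rgs5 (16, 20 and 34) did not pass. In skeletal muscle Tnnt3 was higher (39, 26 and 9) and Myl1 lower (50, 16 and 101; log2 fold change -1.46, and -0.82 without Flag-IP 2), in all 2 higher and 1 lower of 17, or 3 and 1 adjusted over the list alone, with Myh4 at 47, 22 and 14 not passing. The neural adhesion gene Ncam1 was higher with 883, 929 and 292 counts, of which up to 765, 733 and 82 were also counted for the antisense gene Gm11149. The other 10 nerve genes did not pass, Pmp22 (42, 48 and 42) included.

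Immune and blood genes moved singly. Cd74, the invariant chain of antigen presentation, was higher with 69, 42 and 6 counts (3.32 ± 0.56, SE), and the leukocyte gene Ptprc lower (168, 211 and 365), with 13 of 15 lymphoid genes not passing. Adjusted over the list alone H2-Eb1 (32, 20 and 8) was a second higher gene. Of 12 myeloid genes Lgals3 was lower (16, 16 and 47) and the others did not pass, such as Laptm5 (37, 40 and 29) and Mrc1 (85, 70 and 123). Endothelial genes had 0 of 15 past the edgeR threshold, with Eng at 46, 58 and 30, Vwf at 123, 145 and 94 and Emcn at 60, 61 and 102. Blood genes had 0 of 4, with Bpgm at 645, 665 and 477 not passing, although 2 passed adjusted over the list alone. In the male reproductive list Crisp4 was lower (21, 6 and 46; log2 fold change -1.61, and -0.93 without Flag-IP 2) and 9 of 10 did not pass, Adam7 (17, 22 and 36) and Cdh1 (54, 54 and 61) included. Liver genes had 0 of 5 past the threshold and a median of -0.28, which was -0.79 without Flag-IP 2 and 0.85 with no filter.

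Genes of the RNA methylation machinery, to which Fto belongs, had a median of -0.33 with 2 of 19 higher and 2 lower. The writer subunit gene Wtap was lower with 79, 66 and 224 counts (-1.49 ± 0.26, SE) and the reader gene Ythdc2 was lower with 29, 24 and 66, while the reader gene Hnrnpa2b1 was higher with 61, 22 and 16, mostly from Flag-IP 1 (log2 fold change 0.53 without it). Adjusted over the list alone 3 were lower. The median GC of these genes was 44.7%.

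Translation factors had 3 of 28 genes higher and 1 lower, and cytosolic ribosomal proteins 2 of 20 higher and 0 lower. Eif4a2 (148, 70 and 10) and Rps3 (506, 384 and 55) were higher, but small nucleolar RNA genes inside them hold most of those counts: Snora81 has 122, 53 and 0 and Snord15b has 398, 325 and 41. The other higher ribosomal protein gene, Rpl10 (28, 14 and 2), has as many counts embedded as its own, and neither Rps3 nor Rpl10 passed once embedded counts were taken off. The elongation factor gene Eef2 was higher with 44, 33 and 7 counts, and Rps2 (35, 15 and 10) and Rpl24 (19, 28 and 45) did not pass. Without genes that hold a structural RNA gene, the median of the ribosomal protein list went from 0.62 to -0.18. In the secretory pathway 2 of 21 genes were higher, among them Hsp90b1 (42, 37 and 16), with Sec61a1 (35, 41 and 25) and Pdia3 (10, 22 and 30) not passing. Of the stress genes Hsp90ab1 was higher (26, 28 and 8) among 11, although it did not pass adjusted over the list alone, and Bag3 (38, 26 and 22) and Gclm (17, 21 and 36) did not pass. Immediate early genes had 0 of 9 past the edgeR threshold with a median of 0.51 (1.01 without Flag-IP 2, and 0.0074 with total-count scaling). All 9 fold changes lay above 0 in the main fit. No replication-dependent histone gene had enough counts to be tested.

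**Figure D4:**
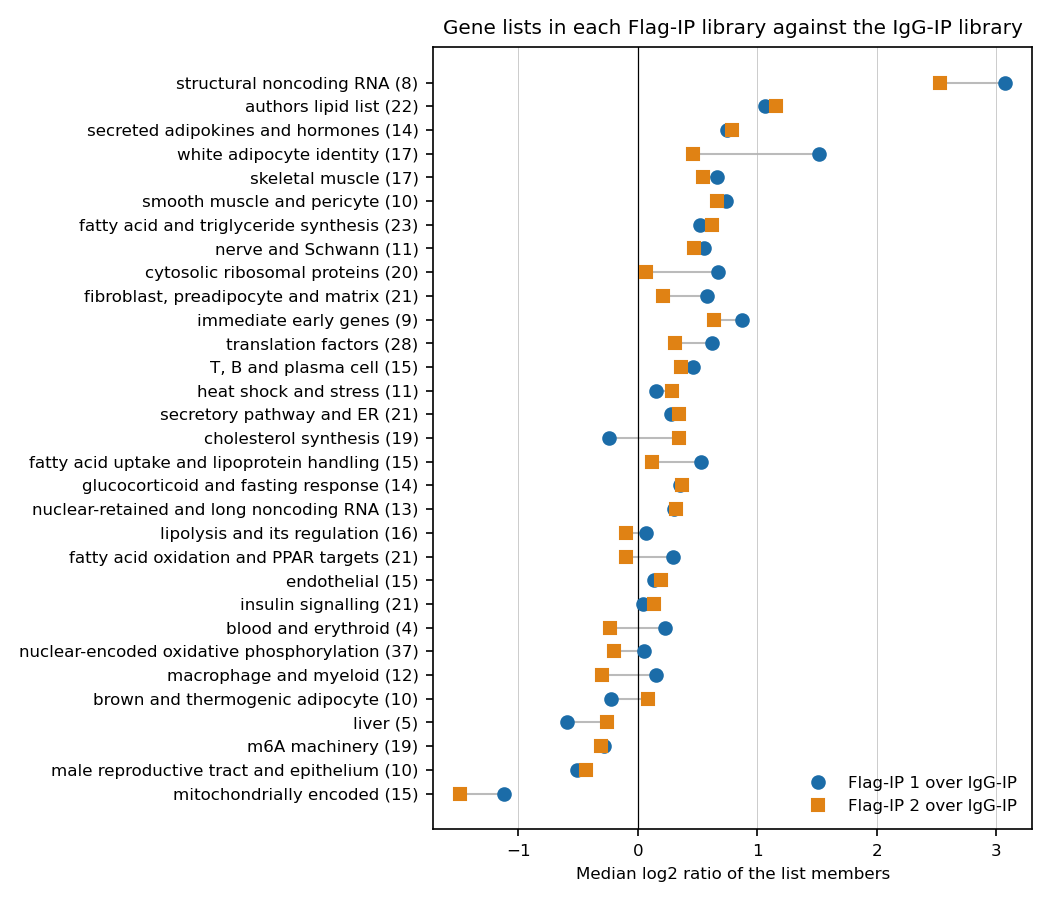
Median log2 ratio of the members of each gene list (horizontal axis) in Flag-IP 1 (circles) and Flag-IP 2 (squares) against the IgG-IP library, with the number of tested members in brackets. Structural noncoding RNAs lie at 3.07 and 2.53 and mitochondrially encoded genes at -1.12 and -1.48, outside the range of the other lists.

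Over all 30 lists with tested members, 5 passed camera with its preset correlation of 0.01, and 0 did with an estimated correlation, for which 1 residual degree of freedom is a weak basis. The camera adjusted p of the other 25 ran from 0.0602 to 0.899. Counts adjusted over the list alone equalled those over all genes except where another count is given. Fry, which asks whether the genes of a list move one way, passed 0 lists.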

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

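Named genes kept their calls to a degree that depended on the setting. Of 68 named genes that passed, 67 still passed with RLE factors, 65 with upper-quartile factors, 61 with scaling to genes under 10000 counts, 59 with the span correction, 53 with total-count scaling and 48 with the GC correction or both corrections, and none turned its direction among those that passed. With DESeq2 26 of the 68 still passed, 3 did not, and 39 had no adjusted p because of its own filter on low counts. The span and GC corrections, the scaling to genes under 10000 counts and the fit without hosts of structural RNA genes were chosen after seeing the data. No paired analysis was possible because the Flag-IP and IgG-IP groups share fewer than 2 replicate numbers. Leaving out a Flag-IP library leaves 1 library against 1, so those values have no test. Depth limits all genes of few counts, with a median of 24, 26 and 25 counts per library. Where a value moved, the cause was not tested, except that total-count scaling shifts every gene by a constant and the filters change which genes are tested.

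DESeq2 called 131 genes higher and 145 lower and gave no adjusted p for 15684 of 17587 genes, and a test against a 1.5-fold change called 331 and 172. Total-count scaling called 342 and 3008, with 822 genes at least 2-fold higher and 2818 at least 2-fold lower in both Flag-IP libraries. Without a filter the rule of size gave 2488 higher, 1406 lower and 5921 apart between the Flag-IP libraries. With a mean of at least 50 counts it gave 264, 144 and 59, and with a prior count of 10 it gave 530, 290 and 467. The span correction left 632 genes lower, the GC correction 411 higher and 353 lower, and both together 492 and 285. Of the 5 lists that passed, 0 did with an estimated correlation and 4 with total-count scaling, where fatty acid synthesis was lost (adjusted p = 0.0524). With no filter 7 lists passed, gaining skeletal muscle (adjusted p = 0.0484) and ribosomal proteins (adjusted p = 0.0309). With a mean of at least 50 counts 2 lists passed (structural noncoding RNA and mitochondrially encoded). Lists passing camera are not counted for the span and GC corrections, since it subtracted those trends more than once.

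With total-count scaling list medians were -0.28 (lipolysis), -0.11 (fatty acid uptake), 0.26 (fatty acid synthesis), -0.079 (cholesterol synthesis), -0.29 (fatty acid oxidation), -0.16 (glucocorticoid), -0.39 (insulin signalling), -0.037 (lymphoid), -0.29 (endothelial), -0.0043 (fibroblast), -0.51 (blood), -0.027 (translation factors), -0.22 (long noncoding), -0.060 (secretory) and -0.022 (heat shock), and Pmp22 was at -0.29. Total-count scaling also gave 0.50 (white adipocyte), 0.55 (adipokines), 0.31 (skeletal muscle), 0.27 (smooth muscle), 0.15 (nerve), 0.099 (ribosomal proteins) and 0.0074 (immediate early). Upper-quartile factors gave 0.0056 (brown fat), 0.031 (myeloid), 0.036 (nuclear oxidative phosphorylation) and 0.025 for Cdh1. Without a filter the medians were 0.27 (brown fat), 1.02 (skeletal muscle), 0.074 (male reproductive), 0.85 (liver), 0.78 (ribosomal proteins) and 0.30 (oxidative phosphorylation). With a mean of at least 50 counts they were -0.30 (white adipocyte), -0.56 (lipolysis), 0.58 (fatty acid synthesis), 0.073 (brown fat), 0.077 (adipokines) and 1.37 (oxidative phosphorylation).

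With the span correction medians were 0.55 (white adipocyte), 0.049 (brown fat), 0.79 (adipokines) and 1.97 (structural noncoding RNA), with Fto at 0.24 and Cdh1 at 0.063. The GC correction gave 0.90 (white adipocyte), 0.36 (fatty acid synthesis), -0.046 (insulin signalling), -0.022 (endothelial), 0.49 (adipokines), 0.58 (translation factors), -0.43 (mitochondrially encoded), 0.55 (long noncoding) and 0.85 (the authors' lipid list), with Laptm5 at -0.093 and Vwf at -0.022. Both corrections gave 0.60 (white adipocyte), 0.35 (fatty acid synthesis), 0.53 (adipokines), 1.34 (structural noncoding RNA) and 0.64 (lipid list), with Fto at 0.27, Laptm5 at -0.10 and Emcn at 0.067. Of 30 list medians, 13 shrank by over 1.5 times and 2 changed sign with the GC correction, 11 and 1 with the span correction, and 20 and 0 with both, while 5, 7 and 6 grew by as much. Without hosts of structural RNA genes the ribosomal proteins were at -0.18, smooth muscle at 0.49 and translation factors at 0.19. With 1 Flag-IP library left out, 2453 to 2582 genes were at least 2-fold higher and 1739 to 1964 lower. Medians that changed sign ran from -0.26 to 0.39 (cholesterol synthesis), -0.10 to 0.36 (fatty acid oxidation), -0.10 to 0.075 (lipolysis), -0.24 to 0.087 (brown fat), -0.32 to 0.17 (myeloid), -0.25 to 0.23 (blood) and -0.22 to 0.057 (nuclear oxidative phosphorylation). Others ran from 0.64 to 1.65 (white adipocyte), 0.084 to 0.81 (ribosomal proteins), 0.22 to 0.60 (fibroblast), 0.13 to 0.60 (fatty acid uptake), 0.33 to 0.64 (translation factors), -0.79 to -0.29 (liver), 0.76 to 1.01 (immediate early), 0.19 to 0.31 (heat shock), 0.14 to 0.20 (endothelial), 0.56 to 0.64 (fatty acid synthesis), 0.89 to 1.03 (adipokines), 2.65 to 3.33 (structural noncoding RNA) and 1.24 to 1.41 (lipid list). Of the genes, Hnrnpa2b1 ran from 0.53 to 2.12, Adora1 from 0.91 to 1.95, Myl1 from -2.58 to -0.82, Col6a1 from -0.23 to 1.99 and Crisp4 from -2.84 to -0.93.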

Other observations

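Further members of the structural noncoding RNA list, not described above, were also higher in the Flag-IP libraries. Rmrp, the RNA of RNase MRP, had 35493, 23240 and 4259 counts (log2 fold change 2.93 ± 0.29, SE), and Rpph1, the RNA of RNase P, had 24024, 16689 and 2562 (3.13 ± 0.29). Scarna2, a guide RNA of Cajal bodies, had 207, 112 and 42 (2.07 ± 0.31). Ribosomal 5S RNA rose less, with Rn5s at 1388, 1078 and 768 counts (0.82 ± 0.23). Among the genes with at least 100000 counts, those named Metazoa_SRP, for signal recognition particle RNA, were higher. They had 443997, 404472 and 79388 counts (log2 fold change 2.55) and 440018, 401173 and 80500 counts (2.52). The pseudogenes Gm12895 (60363, 52036 and 283237) and Gm12896 (56906, 50488 and 275617) were lower. The genes named here were chosen after their values were seen.

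Apart from the tests of embedded reads over all hosts and of a single family, which were written before their results, the tests below were chosen or altered after a result was seen, and the test over all hosts was relabelled as undecided after it. The rule of the GC test was made stricter after its first value was known.

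For the adipocyte marker, adipokine and fatty acid synthesis lists together (51 genes, median 0.77), GC content and span were weighed first. Random lists matched on expression, span and GC had a median of 0.41, and the observed median lay at percentile 99.75. The rule also asked whether the camera calls stayed with both trends removed. Camera subtracted those trends more than once and decides nothing, so this explanation stays open. Those 3 lists were picked because they passed, which raises that percentile beforehand. A contrast with lists of other cell types was run on the same picked lists and is void for that reason, so no biological explanation was tested.

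Counts followed the genomic span of genes, whereas spliced messenger RNA as the main source would tie them to exon length: across 20372 genes Spearman's rho was 0.87, 0.88 and 0.91 with span and 0.60, 0.60 and 0.59 with exon length, a gap of at least 0.261, so it does not account for the counts. Mitochondrial DNA was weighed because mt-Nd6, on the other strand, had at least 2.88 times the counts per base of mt-Co1 in every library (2.93, 3.36 and 2.88). Even coverage by DNA would give equal counts per base. The ratio was also lowest in IgG-IP, so it cannot show that DNA was most abundant there. Messenger genes were uneven in IgG-IP, from 0.346 counts per base (mt-Co3) to 2.03 (mt-Nd6), with 1.40 for mt-Nd5 and 1.44 for mt-Cytb. The rule for mt-Nd6 weighed none of this and decides nothing. Transfer RNA genes had 0.465, 0.434 and 1.84 counts per base and messenger genes 0.398, 0.375 and 1.01. DNA, most of it in IgG-IP, stays a possible reason for their decrease, but no strand or read position was used here to test it. Olfactory and vomeronasal receptor genes, usually silent outside the nose, had 0.308, 0.306 and 0.247 and 0.324, 0.376 and 0.706 counts per kb of span. All nuclear protein-coding genes, the most highly counted left out, had 0.957, 1.00 and 1.11. Part of the nuclear counts could therefore also be DNA, although of the receptor genes only the vomeronasal ones were highest in IgG-IP. DNA and unspliced RNA were not told apart for nuclear genes, whose counts and fold changes are open to either reading, and no biological explanation was tested.

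Of genes called higher, 83 hold a structural RNA gene, and 50 of those have embedded counts in some library. Outside the small RNA classes, such hosts were 9.76% of genes called higher, 16.9% of those called lower and 6.46% of the others. Among the 24 hosts with at least 50% of their Flag-IP counts embedded, such as Tex14 and Ss18, 1 was still called once these were taken off. Their median log2 fold change went from 2.25 to 0, which fits embedded reads. Hosts picked by that share often keep few counts, so the loss of their calls was likely beforehand. In the other 26 the embedded share (at most 16.3%) lay at least 37.7 points under the share by which Flag-IP exceeded IgG-IP, so embedded reads do not account for them, while the subtraction over all 50 (27 still called) moved these hosts too little to decide anything. The test of a single family took the annotated rRNA class as that family. Outside it, 75 of 89 structural genes were higher (84.3%), so the increase was not confined to that class. Genes were not grouped by sequence, and the other classes also hold similar copies. Whether near-identical copies shared reads there stays open. No biological explanation was tested, and structural RNA that FTO carries and RNA that the Flag antibody or beads hold would look the same here.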
